A study of Homo sapiens with 2 samples.

How the data were processed

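RNA sequencing of polyadenylated RNA was made from HCT116 cells, an established human colorectal carcinoma line, treated for 8 h with 1 µM CB-5083 or with the solvent DMSO. Each treatment was 1 library. Stranded mRNA libraries were prepared with a commercial kit, per the labels' protocols. The submitters' processing notes name RSEM 1.2.0 and the genome build hg19. The aligner is not given in the sources used here.

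The deposited values are a signal per gene: estimated counts that the authors scaled within each library, although the column names call them counts. From the values themselves, the 75th percentile over all genes, zeros included, lay at 999.73 in the DMSO library and 999.89 in the CB-5083 library, so 1000 was the target of the scaling. The commonest low values were multiples of 1 step per library, 1.079 with DMSO and 1.1752 with CB-5083. Dividing by that step gave back estimated counts. Of the low values, up to 5, 78.1% and 79.1% came out whole within a tolerance of 0.02, and of all values above 0, 55.0% and 55.7%. The rest were fractions, as RSEM gives for reads shared between genes, so the recovered values are estimates and not whole reads. The authors' deposited log2 ratio (another column of the series table) equals log2 of the CB-5083 value over the DMSO value, with no pseudocount, to within 2.4e-09, and held a number for 16034 genes and spreadsheet error text for the other 5081. The design, fixed before the data were examined, had assumed unscaled estimated counts or TPM. The files hold the scaled signal instead, so CPM were computed from the recovered estimated counts.

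The files held 21116 rows. 1 row without a value was left out, which left 21115 genes. A spreadsheet had turned 27 gene symbols into dates, and 26 of these were resolved through their RefSeq accessions. Current names for 17996 genes came from name tables, 15938 by symbol, 1629 by accession and 429 by synonym. Coordinates are those of the files (hg19), with starts counted from 1. The reference annotation used here, GENCODE release 29, is on another build and served only for transcript length and GC content.

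Estimated counts were turned into CPM, which divide a gene's count by its library's total, with TMM factors of 1.1258 for DMSO and 0.8883 for CB-5083, computed with a trim of 30% on ratios and 5% on means. The log2 ratio of a gene is log2 of (CB-5083 + 1) over (DMSO + 1), in CPM, which understates the difference of genes with low values. A gene counted as higher or lower when this ratio was at least 1 in size, that is 2-fold, and the gene reached 5 CPM in at least 1 library. With 1 library per group there was no test between conditions and no p-value. Each fold, computed without the pseudocount, has a 95% exact (Clopper-Pearson) interval from the estimated counts of both libraries, which covers counting error only.

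36 gene lists were fixed before the data were examined. Some genes are on more than 1 list, so the lists are not independent of each other. A member was measured when its mean over both libraries was at least 1 CPM. The median log2 ratio of a list with at least 3 measured members was ranked among the medians of 10000 random lists of the same size, matched on mean expression in 20 bins drawn from 11964 genes. That rank describes these libraries and is no test between treatments. No symbol of the list of mitochondrially encoded genes was matched, and that list was not analysed here.

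The genes named in the text were chosen by a rule fixed before the data were examined. It takes VCP, the 12 genes with the highest and the 12 with the lowest log2 ratio among those with at least 10 CPM in 1 library, and up to 4 measured members of each list by the size of the ratio. It adds the most expressed member of each list and ATF4, DDIT3, HSPA5, XBP1, HERPUD1, SQSTM1, CDKN1A, TNFRSF10B, HMOX1, HSPA1A, NFE2L1 and MYC, among others. The rule gave 175 genes, of which those that bear on each list are named. Some of the genes it takes are not reported here.

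The scripts were tested on simulated data for the comparison of CB-5083 with DMSO over 21115 genes, with 200 genes altered. The altered genes were drawn from those with a mean of at least 10 CPM. Both simulated libraries carried counting error only, and no variation between cultures was simulated. The test therefore checks the scripts and gives no rate of false calls for the real libraries. All 100 genes altered 4-fold were called, 0 of the 100 genes altered 1.5-fold, and 0 of 8817 unaltered genes. The intervals held the true fold in 95.3% of the unaltered genes, and those of the altered genes were not checked. Of 200 unaltered lists, 11 lay outside the central 95% of random lists.

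Alternatives to the scaling, pseudocount, filter, fold threshold, counting interval, source of the ratio, expression bins and list membership were run 1 at a time, and the closing section gives their effect. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.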

Results

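Gene expression was measured in HCT116 cells after 8 h with 1 µM CB-5083 or with DMSO. CB-5083 inhibits p97, the ATPase encoded by VCP that pulls ubiquitinated proteins out of membranes and complexes, among them misfolded proteins of the endoplasmic reticulum (ER), before the proteasome degrades them. Each treatment was 1 library, so no difference below has a replicate check. The DMSO library held 29273755 estimated counts and the CB-5083 library 31997748, with 17310 and 16729 of 21115 genes above 0. A value of 0 allows up to 3 counts, which is 0.091 CPM with DMSO and 0.106 CPM with CB-5083.

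The comparison of CB-5083 with DMSO asked which transcripts differed when p97 was inhibited. With CB-5083, 24 of 30 measured ER chaperones and folding enzymes, 21 of 25 targets of the stress factors ATF4 and CHOP and 12 of 23 genes of amino acid supply were higher (18, 17 and 9 with library totals). Of the measured members of these lists, 1, 10 and 3 are on another list too, so the counts are not independent. Of 13 measured WNT target genes 7 were lower (8 with library totals). Most cell cycle genes lay within 2-fold, with list medians below those of random lists. HSPA5, the main chaperone of the ER lumen, went from 1282 CPM with DMSO to 21303 CPM with CB-5083, a 16.6-fold difference (95% counting interval 16.5 to 16.8). DDIT3, which encodes the stress transcription factor CHOP, had the highest ratio of the genes named here, at 6.16 against 351 CPM (57.0-fold, 49.6 to 65.8). AXIN2, a feedback inhibitor and direct target of WNT signalling, had the lowest, at 18.0 against 0.774 CPM (23.2-fold lower, 15.2 to 37.3).

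Of 9543 genes with at least 5 CPM in 1 library, 689 were at least 2-fold higher and 469 at least 2-fold lower with CB-5083, while 70.1% lay within 1.5-fold. At 4-fold, 115 genes were higher and 34 lower. The counting interval excluded a fold of 1 for all 1158 genes past the 2-fold threshold. At this depth the threshold and the filter fix that in advance, so it lends these genes no support. Scaling by library totals moved the median of all genes by -0.33 on the log2 scale and gave 371 higher and 994 lower genes, and the authors' deposited log2 ratio gave 636 and 722. Directions are therefore given on the TMM scale, and lists whose median turns sign under another scaling are named as such.

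**Figure D1:**
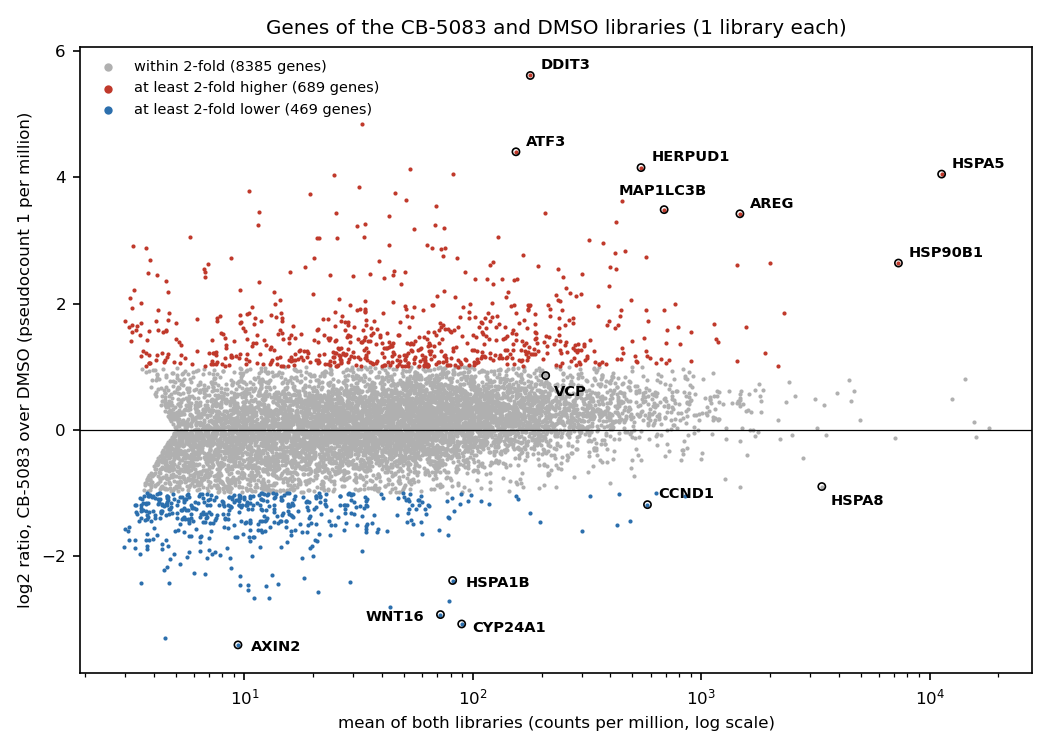
Mean of both libraries in CPM (log axis) against the log2 ratio of CB-5083 over DMSO for 9543 genes, 1 point per gene. Red points are the 689 genes at least 2-fold higher and blue points the 469 at least 2-fold lower, with HSPA5 at 4.05 and AXIN2 at -3.42 (with library totals the split is 371 and 994).

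VCP itself, on chromosome 9 from 35056065 to 35072739 in hg19, was at 148 CPM with DMSO and 269 CPM with CB-5083 (1.81-fold, 1.75 to 1.88), short of the 2-fold threshold. Of 34 measured genes of p97 and its cofactors, 2 were higher, none lower and 32 neither. SELS, an ER membrane protein that recruits p97, was 3.49-fold higher (3.29 to 3.70), and ZFAND1, a cofactor of p97 at stress granules, 2.05-fold higher (1.99 to 2.11), the latter with a log2 ratio of 0.69 by library totals and 0.94 in the authors' deposited table. The list's median log2 ratio of 0.30 turned to -0.04 with library totals, which left 1 member higher, and 9576 of 10000 matched random lists had a lower median.

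The ATF4 and CHOP targets, genes of the integrated stress response, had the highest median of any list. Of 25 measured members 21 were higher, none lower and 4 neither, with a median log2 ratio of 1.94 above that of all 10000 random lists. Besides DDIT3, the transcription factor gene ATF3 was at 12.99 against 296 CPM (22.8-fold, 20.7 to 25.2). PPP1R15A, whose product brings a phosphatase to eIF2alpha, was 18.5-fold higher (16.4 to 20.9), and SESN2, a stress-induced inhibitor of mTORC1, 18.4-fold higher (15.2 to 22.6). ATF4 itself was 2.10-fold higher (2.04 to 2.16), but its log2 ratio was 0.73 with library totals and 0.98 in the authors' deposited table, below the threshold.

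Genes of amino acid synthesis and transport gave 12 higher, none lower and 11 neither of 23 measured, and 10000 of 10000 random lists had a median below their 1.16. SLC7A11, the cystine importer, was 8.12-fold higher (7.77 to 8.48), GOT1, the cytosolic aspartate aminotransferase, 7.91-fold (7.60 to 8.23) and ASNS, asparagine synthetase, 6.74-fold (6.54 to 6.95). SLC38A2, a neutral amino acid transporter, was the most expressed, at 999 against 3609 CPM. Among 20 measured cytosolic tRNA synthetases 9 were higher and 11 neither (median 0.88, above all random lists), and 6 were higher with library totals (median 0.54). WARS, SARS, CARS and GARS, which charge tRNAs for tryptophan, serine, cysteine and glycine, were 4.78-fold (4.59 to 4.97), 4.45-fold (4.27 to 4.64), 3.91-fold (3.66 to 4.17) and 3.71-fold (3.63 to 3.80) higher. IARS, the most expressed synthetase, was at 609 against 1151 CPM.

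ER chaperones and folding enzymes gave 24 higher, none lower and 6 neither of 30 measured, with a median of 1.52 above all random lists. HYOU1, a nucleotide exchange factor for HSPA5, was 9.87-fold higher (9.48 to 10.3) and DNAJB9, its J-domain cochaperone, 8.61-fold (8.02 to 9.24). HSP90B1, the HSP90 of the ER, was at 2017 against 12596 CPM (6.25-fold, 6.19 to 6.30). HSPA5 alone took 0.144% of the estimated counts with DMSO and 1.89% with CB-5083. Of 14 measured sensors and factors of the unfolded protein response, 9 were higher and 5 neither (median 1.38, above all random lists), and 6 were higher with library totals. EIF2AK3, the kinase PERK, was 6.88-fold higher (6.35 to 7.46), CREB3L2, a membrane-bound transcription factor, 3.96-fold (3.77 to 4.17) and XBP1, the transcription factor spliced by IRE1, 3.25-fold (3.11 to 3.41). ERN1, which encodes IRE1, was at 1.03 against 5.24 CPM, and lay under the filter with library totals.

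Of 33 measured genes of ER-associated degradation, in which p97 acts, 11 were higher, none lower and 22 neither, and 9999 of 10000 random lists had a median below their 0.57. With library totals 8 were higher and the median was 0.23. HERPUD1, a membrane organiser of this pathway, was at 57.0 against 1033 CPM (18.1-fold, 17.3 to 19.0). SEL1L and SYVN1, adaptor and ubiquitin ligase of a shared complex, were 7.15-fold (6.90 to 7.40) and 6.11-fold (5.504 to 6.80) higher, and SELK, a selenoprotein of the ER membrane, 5.83-fold (5.43 to 6.28). ER translocation and secretory transport genes gave 16 higher, none lower and 30 neither of 46 (median 0.77, above all random lists), and 6 higher with a median of 0.43 with library totals. SEC24D and SEC23B, parts of the COPII coat, were 6.92-fold (6.54 to 7.33) and 2.67-fold (2.57 to 2.76) higher, and SEC11C, a subunit of signal peptidase, 2.998-fold (2.81 to 3.20).

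**Figure D2:**
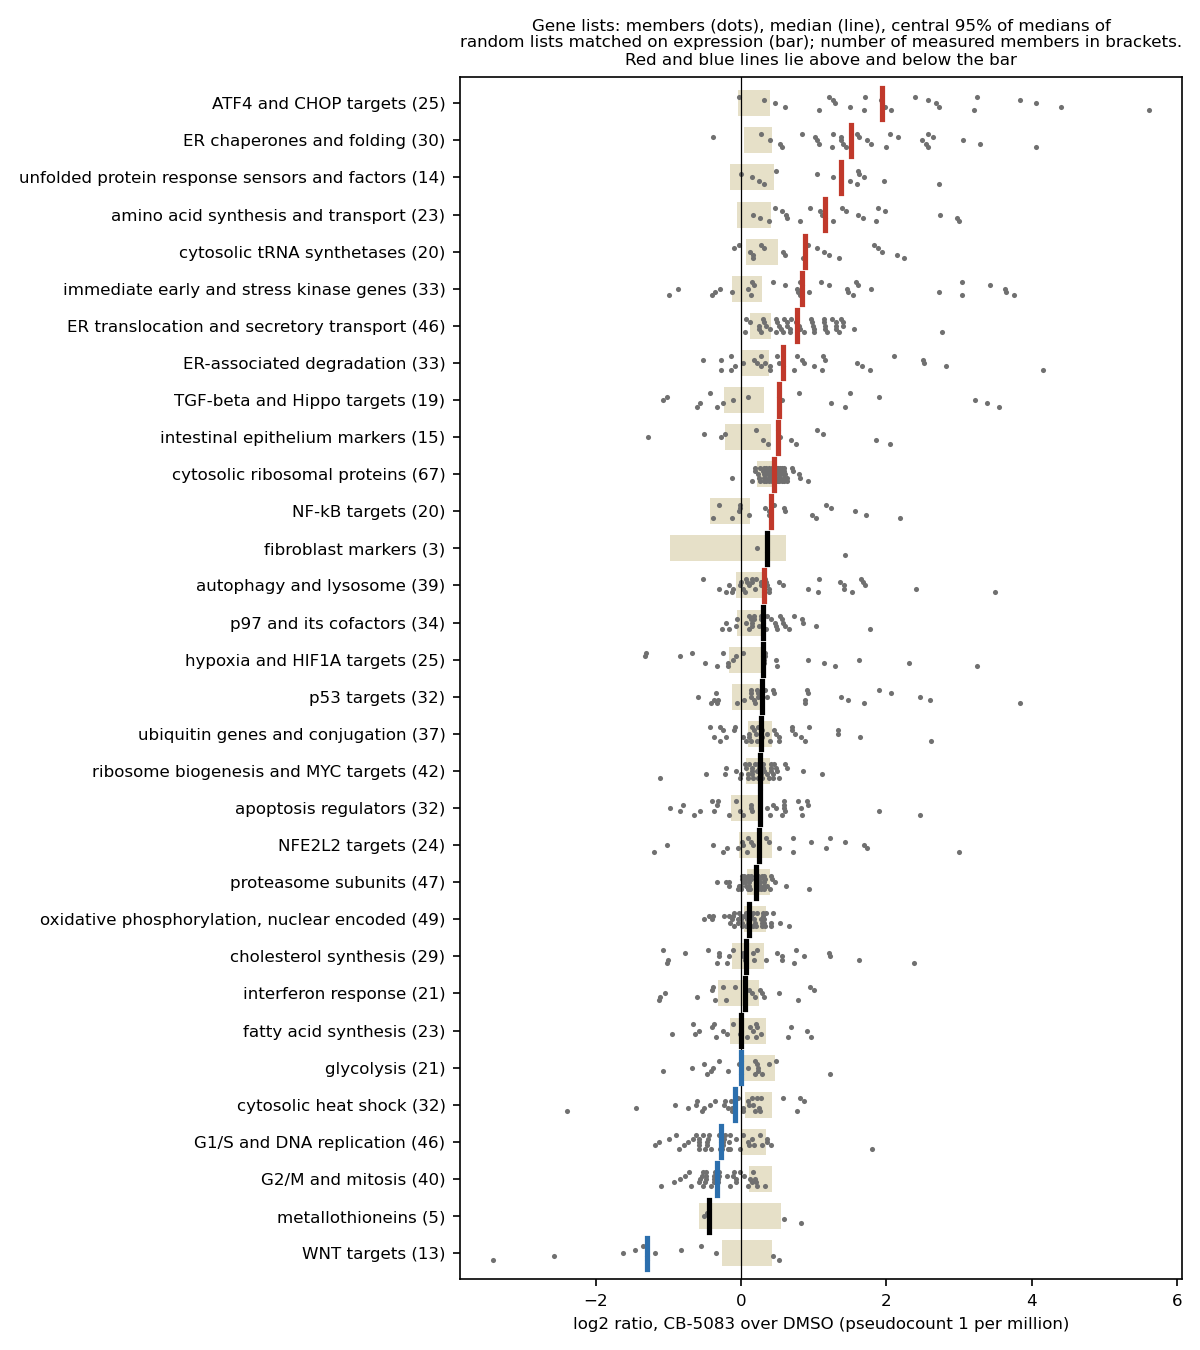
Log2 ratio of CB-5083 over DMSO for the measured members (dots) of 32 gene lists, with each list's median (line) and the central 95% of the medians of 10000 random lists matched on expression (bar). 13 medians lie above and 5 below that range, from 1.94 for ATF4 and CHOP targets to -1.29 for WNT targets. Among the lists outside that range, the median of autophagy and lysosome genes turned from 0.32 to -0.02 with library totals. That of glycolysis genes turned from -0.005 to 0.01 with median-of-ratios scaling. Medians of several lists inside the range turned sign under another scaling too.

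Of 32 measured genes of the cytosolic heat shock list 1 was lower, none higher and 31 neither, and 1 of 10000 random lists had a median below their -0.08. With library totals 3 were lower and the median was -0.41. HSPA1B, an inducible HSP70 gene, was at 138 against 25.4 CPM (5.43-fold lower), although reads from its near-identical copy HSPA1A, listed at 0 in both libraries, cannot be told from its own. HSPA8, the constitutive HSP70, was at 4399 against 2349 CPM (1.87-fold lower, 1.86 to 1.89), and HSP90AA1 at 7377 against 6745 CPM. DNAJB4, a J-domain cochaperone, was 1.84-fold higher (1.73 to 1.96), within the threshold.

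None of 47 measured proteasome genes passed 2-fold in either direction. Their median of 0.20, which turned to -0.13 with library totals, lay above that of 3187 of 10000 random lists. NFE2L1, the transcription factor that induces proteasome genes and is processed with the help of p97, was 1.91-fold higher (1.83 to 1.999), and PSMC4, an ATPase subunit, 1.55-fold (1.45 to 1.65). Of 37 measured ubiquitin and conjugation genes 4 were higher and 33 neither (median 0.27, with 5459 random lists lower), and with library totals 2 were higher and the median was -0.06. Among these were UBB, a polyubiquitin gene at 387 against 1203 CPM whose value is uncertain because its repeats share sequence with other genes, RNF19A (2.56-fold, 2.39 to 2.74) and UCHL3 (2.55-fold, 2.38 to 2.73). RNF19A and UCHL3 were just short of the threshold with library totals, at log2 ratios of 0.995 and 0.992.

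Autophagy and lysosome genes gave 11 higher, none lower and 28 neither of 39, and their median of 0.32 (-0.02 with library totals) exceeded 9873 random lists, but stood at percentile 97.02 among members of at least 5 CPM. MAP1LC3B, which encodes an LC3 protein of the autophagosome membrane and shares sequence with MAP1LC3B2, was at 112 against 1265 CPM (11.3-fold). WIPI1, a phosphoinositide-binding autophagy protein, was 5.67-fold higher (5.09 to 6.33), the transcription factor gene TFE3 3.67-fold (3.06 to 4.43) and GABARAPL1, an LC3 relative, 3.38-fold (3.10 to 3.68). SQSTM1, the autophagy receptor p62, was at 58.5 against 87.4 CPM (1.49-fold, 1.41 to 1.58). NFE2L2 targets, the antioxidant genes, gave 6 higher, 2 lower and 16 neither of 24 (median 0.25, with 6672 random lists lower), and with library totals 4 were higher, 2 lower and the median was -0.09. UGDH, GCLC and TXNRD1, enzymes of glucuronate, glutathione and thioredoxin metabolism, were 3.36-fold (3.24 to 3.48), 3.26-fold (3.15 to 3.38) and 2.70-fold (2.66 to 2.74) higher. HMOX1, haem oxygenase, was at 5.28 against 13.1 CPM, with a log2 ratio of 1.17 that was 0.86 with library totals. No metallothionein list member passed 2-fold of 5 measured (median -0.45, and -0.77 with library totals, with 619 random lists lower, but at percentile 1.98 among lists matched on GC content and length too), with MT1E at 57.9 against 41.4 CPM.

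p53 targets gave 8 higher, none lower and 24 neither of 32 (median 0.28, and -0.06 with library totals, with 9735 random lists lower). GADD45A, a growth arrest gene, was 6.24-fold higher (5.84 to 6.66), TNFRSF10B, the death receptor DR5, 5.58-fold (5.36 to 5.80), GDF15, a stress-induced cytokine, 4.81-fold (4.05 to 5.75) and CDKN1A, the cell cycle inhibitor p21, 2.65-fold (2.47 to 2.84). Of the 32 measured p53 targets, 8 are on another list, among them SESN2 and GDF15, which are on the list of ATF4 and CHOP targets. Of 32 measured apoptosis regulators 2 were higher, TNFRSF10B and PMAIP1, the BH3-only gene NOXA (3.76-fold, 3.62 to 3.91), and 30 neither (median 0.25, with 9668 random lists lower), whereas with library totals 2 were higher, 2 lower and the median was -0.05. BCL2, which opposes apoptosis, was at 3.13 against 1.09 CPM and BIRC5, which encodes survivin, at 153 against 85.4 CPM.

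Immediate early and stress kinase genes gave 15 higher, none lower and 18 neither of 33, with a median of 0.83 above all random lists. With library totals 13 were higher and 2 lower. DUSP1 and DUSP5, phosphatases that switch off MAP kinases, were 15.8-fold (13.6 to 18.5) and 12.6-fold (12.04 to 13.2) higher, and HBEGF, an EGF receptor ligand, 14.2-fold (12.4 to 16.4). AREG, another such ligand, was at 251 against 2704 CPM, over a locus that holds a duplicate copy and leaves its value uncertain. EREG was at 1146 against 2662 CPM, with a log2 ratio of 0.87 by library totals against 1.21. Of 20 measured NF-kB targets 4 were higher and 16 neither (median 0.42, above all random lists, but at percentile 89.95 among members of at least 5 CPM), and the median was 0.15 with library totals. IL8, a chemokine, was at 1.03 against 8.27 CPM, and PTGS2, a cyclooxygenase, at 1.36 against 6.83 CPM. TGF-beta and Hippo targets gave 7 higher, 1 lower and 11 neither of 19 (median 0.52, and 0.19 with library totals, with 9993 random lists lower). CYR61 and CTGF, matricellular targets of YAP, were 12.8-fold (11.5 to 14.4) and 10.97-fold (9.37 to 12.9) higher.

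WNT targets were the list with the lowest median, -1.29, and none of 10000 random lists had a lower one. Of 13 measured members 7 were lower, none higher and 6 neither. After AXIN2, BMP4, a secreted morphogen, was 6.92-fold lower (5.84 to 8.26). RNF43 and ZNRF3, ubiquitin ligases that remove WNT receptors, were 3.23-fold (2.91 to 3.59) and 2.98-fold (2.56 to 3.49) lower, and CCND1, cyclin D1, was at 810 against 354 CPM (2.29-fold lower, 2.24 to 2.34). MYC, also on this list, was at 198 against 268 CPM, and CD44, a cell surface glycoprotein, at 804 against 634 CPM.

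Most cell cycle genes did not pass the 2-fold threshold. G1/S and DNA replication genes had a median of -0.27 and G2/M and mitosis genes one of -0.34, each below all 10000 random lists. In the first list 1 of 46 measured members was higher, 2 were lower and 43 neither. CDC6, a loader of the replicative helicase, was 3.51-fold higher (3.41 to 3.61), while FEN1, the flap endonuclease, was 2.22-fold lower (2.10 to 2.35) together with CCND1. In the second list 1 of 40 was lower, none higher and 39 neither. That gene was DLGAP5, a spindle protein (2.15-fold lower, 2.06 to 2.25), and AURKA, a mitotic kinase, was 1.91-fold lower (1.81 to 2.01). With library totals 8 and 6 members of these lists were lower and the medians were -0.61 and -0.67.

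None of 67 cytosolic ribosomal protein genes passed 2-fold, and their median of 0.45 lay above 9833 random lists, but at percentile 96.8 with 100 expression bins, and inside the central 95% of random lists among members of at least 5 CPM. The median was 0.11 with library totals. RPL10A had the highest ratio, at 513 against 975 CPM. Ribosome biogenesis and MYC targets gave 1 higher, 1 lower and 40 neither of 42 (median 0.26, and -0.06 with library totals, with 6310 random lists lower). RRP12, a ribosome export factor, was 2.25-fold higher (1.997 to 2.54) with a log2 ratio of 0.79 by library totals, and UBTF, a factor of RNA polymerase I, 2.21-fold lower (2.05 to 2.39). None of 49 nuclear genes of oxidative phosphorylation passed 2-fold (median 0.11, and -0.23 with library totals, with 1512 random lists lower), with ATP5B at 946 against 1262 CPM.

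Glycolysis genes gave 1 higher, 1 lower and 19 neither of 21. Their median of -0.005, which turned to 0.01 with median-of-ratios scaling, lay above 230 of 10000 random lists and inside the central range under 4 of 9 alternatives. With library totals none was higher, 2 were lower and the median was -0.35. HK2, a hexokinase, was at 103 against 244 CPM, with a log2 ratio of 1.23 that was 0.89 by library totals, and SLC16A3, a lactate exporter, at 12.4 against 5.35 CPM. Hypoxia and HIF1A targets gave 5 higher, 2 lower and 18 neither of 25 (median 0.30, with 9683 random lists lower), and with library totals 3 were higher, 2 lower and the median was -0.03. Over 9 alternatives the percentile of this list ran from 18.92 to 97.53. DDIT4, an mTORC1 inhibitor that ATF4 also induces, was 10.2-fold higher (9.20 to 11.3) and NDRG1 5.08-fold (4.79 to 5.40), whereas EGLN3, a HIF prolyl hydroxylase, was 3.23-fold lower (2.41 to 4.39).

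Cholesterol synthesis genes gave 4 higher, 2 lower and 23 neither of 29, with 3657 random lists below their median of 0.06, which turned to -0.26 with library totals and -0.02 with upper quartile scaling. The balance of calls turned too, to 2 higher and 4 lower with library totals, while upper quartile scaling gave 4 higher and 3 lower. STARD4, a sterol carrier, was 5.35-fold higher (5.01 to 5.73) and INSIG2, which retains the sterol sensor in the ER, 3.14-fold (2.93 to 3.36). HMGCS1, an early enzyme of the pathway, was at 146 against 340 CPM, with a log2 ratio of 1.21 that was 0.87 by library totals. None of 23 fatty acid synthesis genes passed 2-fold (median -0.004, which turned to 0.01 with median-of-ratios scaling, and 1999 random lists lower), with SCD, a desaturase, at 1641 against 1636 CPM. With library totals 1 was lower and the median was -0.34. Interferon response genes gave none higher, 3 lower and 18 neither of 21 (median 0.05, and -0.23 with library totals, with 7386 random lists lower). OAS3, IFIH1 and TAP1, genes of RNA sensing and antigen processing, were 2.24-fold (2.04 to 2.47), 2.55-fold (1.99 to 3.29) and 2.23-fold (1.88 to 2.65) lower.

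Intestinal epithelium markers, the list closest to the origin of the line, gave 4 higher, 1 lower and 10 neither of 15 (median 0.50, 9948 random lists lower), and with library totals 2 were higher, 1 lower and the median was 0.17. KLF5, a transcription factor of intestinal crypts, was 4.19-fold higher (4.03 to 4.37) and CDH1, E-cadherin, 3.65-fold (3.48 to 3.83). Few markers of other cell types were measured. Of 3 measured fibroblast markers 1, FN1, was higher at 6.15 against 18.2 CPM (list median 0.35, and 0.09 with library totals, with 9272 random lists lower). Of the haematopoietic markers LCP1 was at 1.15 against 5.28 CPM and CD68 at 1.30 against 2.01 CPM, of the endothelial markers ESAM was at 1.73 against 1.44 CPM, and of the neuronal and hepatocyte markers MAP2 was at 9.25 against 19.7 CPM and TUBB3 at 5.79 against 4.08 CPM.

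Other genes of the highest and lowest ratios belonged to none of these lists. C9orf150, now named LURAP1L, was at 1.28 against 64.5 CPM (50.2-fold, 37.3 to 70.5). UPP1, uridine phosphorylase, was 24.5-fold higher (19.1 to 32.0). Among the lowest, CYP24A1, the vitamin D hydroxylase, was at 161 against 18.0 CPM (8.91-fold lower, 8.13 to 9.77) and WNT16, a WNT ligand, at 128 against 15.9 CPM (8.08-fold lower, 7.33 to 8.92). SOX4, a transcription factor, was 7.67-fold lower (6.78 to 8.70) and PDE4B, a cAMP phosphodiesterase, 6.86-fold (6.29 to 7.50). VSNL1, ZNF503, TRERF1, TRIB2, ITGB8 and C9orf140 were lower by 8.77-fold, 8.37-fold, 7.91-fold, 7.51-fold, 7.10-fold and 6.68-fold.

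**Figure D3:**
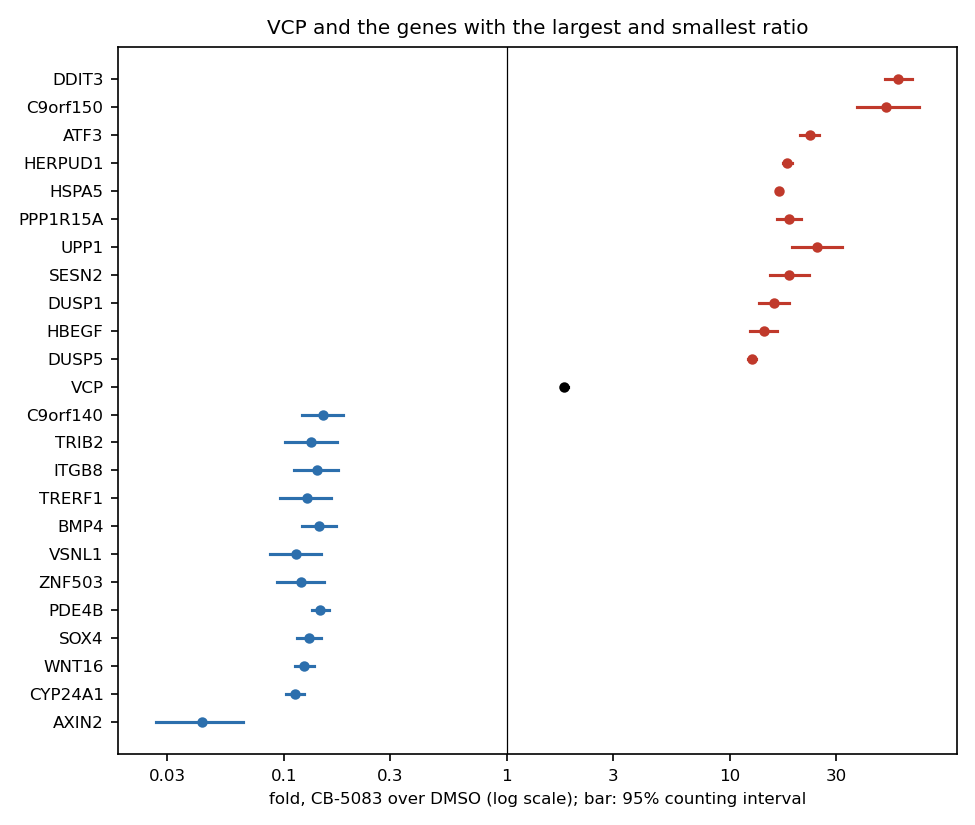
Fold of CB-5083 over DMSO (log axis) with its 95% counting interval for VCP, for 11 of the 12 genes with the highest and for the 12 with the lowest log2 ratio, 1 library per treatment. DDIT3 lies at 57.0 and AXIN2 at 0.0431. No interval shown reaches 1, which for all genes but VCP follows from their choice by extreme ratio.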

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

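Scaling by library totals gave 371 genes at least 2-fold higher and 994 lower, against 689 and 469. All 371 were among the 689, and all 469 among the 994, which follows nearly by construction, since a scaling shifts all ratios together. Thresholds of 1.5-fold gave 1660 and 1195 genes and of 4-fold 115 and 34, by construction. The count of lower genes was 198 with a pseudocount of 5 CPM, 179 with a filter at 20 CPM and 722 by the authors' deposited log2 ratio, which lacks a pseudocount and is scaled by the upper quartile. A larger pseudocount shrinks ratios and the filter keeps fewer genes by construction. The loss was uneven, however, since the higher genes numbered 518 with that pseudocount and 561 with that filter, which kept 6559 genes. Across 9127 genes at the main filter with known GC content and length, mean expression and log2 ratio had a Spearman correlation of 0.321. Lower ratios were thus more common among less expressed genes, and what lies behind this trend was not tested. The cause was not tested further for the authors' ratio. The other 13 values of these counts stayed within 1.5 times, but some had to. Requiring a counting interval beyond 1 could not alter the counts, as said above. Without a filter the counts, 751 and 652, had to equal those with a filter at 1 CPM. The pseudocount keeps any gene under 1 CPM in both libraries short of 2-fold. Of the 18 lists outside the central range of random lists, 14 kept their side under all 9 alternatives, and the exceptions were autophagy, NF-kB targets, ribosomal proteins and glycolysis. The rank sets a list against random lists of the same ratios, so a common shift moves both nearly alike. The scalings, and the authors' ratio as far as its scaling goes, could therefore hardly change a side and lend the sides little support. Among these 18 lists, the median of autophagy and lysosome genes turned to -0.02 with library totals and that of glycolysis genes to 0.008 with median-of-ratios scaling. Both turns follow by construction from the common shift of a scaling, which moved the median of all genes by -0.328 and 0.011. Medians of several lists inside the range turned sign likewise, as given with each list above. Of 14 lists inside the range, 4 left it under at least 1 alternative (p53 targets, apoptosis regulators, hypoxia targets and fibroblast markers). With random lists matched on GC content and length too, 1 more list left it, the metallothioneins at percentile 1.98, and all 18 stayed outside. Of 107 named genes past 2-fold, 91 stayed past it with library totals, 104 by the authors' ratio and all 107 with median-of-ratios scaling. None changed sign under these or a pseudocount of 0.1 CPM, but that outcome was fixed in advance. Common shifts this small cannot turn a 2-fold ratio, and a pseudocount never alters its direction. The shift of 0.011 could likewise drop only genes right at the threshold. TPM values as deposited were planned as an alternative and not run, since no TPM was among the values used here. No paired analysis was possible because each group holds 1 library. At 0.091 and 0.106 CPM for 3 counts, depth limits genes under about 1 CPM.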

Other observations

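The families in the next paragraph, the HOX genes and the tests of counting error, of other differences between the cultures, of shared reads and of scaling were chosen after the results were seen. The tests of GC content and transcript length were set before their outcome was seen.

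Genes were grouped by the stem of their symbol, and 178 families had at least 8 measured members. The median log2 ratio of 17 families lay above and that of 15 below the central 95% of random lists matched on expression, where 8.9 would lie outside by chance. SNHG genes, hosts of small nucleolar RNAs, had a median of 0.55 over 14 members (0.21 with library totals), with SNHG5 at 54.6 against 182 CPM and SNHG1 at 390 against 1015 CPM. Keratins had a median of 0.57 over 11 members (0.24 with library totals), with KRT7 at 2.28 against 10.1 CPM and KRT80 at 4.49 against 17.7 CPM. CBX genes, readers of histone methylation, had a median of -0.66 over 8 members, with CBX6 and CBX2 lower by 3.09-fold and 3.23-fold. Among the ADAM metalloproteases (median -0.70 over 9), ADAM19 was 5.92-fold lower, whereas ADAM17, a sheddase of EGF receptor ligands, was at 50.1 against 184 CPM.

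Of 13 measured WNT targets 7 were at least 2-fold lower and none 2-fold higher. Across 9127 genes, GC content and log2 ratio had a Spearman correlation of -0.152, so a weak GC trend exists in these libraries. GC content or transcript length bias is argued against as the source, since the median stayed at percentile 0 among lists matched on expression, GC content and length. That matching was coarse, with 5 bins of GC content and 3 of length. The counting interval lay wholly below 1 for 11 of the 13 members and wholly above 1 for the other 2. For the 7 called lower, the threshold and filter fix this in advance, so the interval adds nothing for them. For the members not called, it argues against counting error alone as the source of their ratios. With 1 library per group, a difference between the cultures other than the drug cannot be told apart from an effect of the drug.

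HSPA1B was 5.43-fold lower, whereas 24 of 30 measured ER chaperones and folding enzymes were higher (18 with library totals). Under 4 scalings the log2 ratio of HSPA1B ran from -2.73 to -2.38, so it stayed past 2-fold under each. A scaling shifts genes together, and here by too little to reach the threshold. That outcome was therefore fixed in advance, and no conclusion on scaling is drawn from it. The summed values of HSPA1A, HSPA1B and HSPA1L had a log2 ratio of -2.39, but 4542 of the 4555 estimated counts with DMSO and 721 of the 725 with CB-5083 stand in the HSPA1B row, so this sum decides nothing on shared reads. Whether transcripts of HSPA1B or of HSPA1A were lower cannot be told apart here, since their reads are shared. Whether the DMSO culture had a raised level stays open.

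HOX genes, which set positional identity, had a median log2 ratio of -0.85 over 22 measured members (-1.16 with library totals), of which 7 were at least 2-fold lower and 1 higher. HOXA5 was 4.05-fold lower (3.07 to 5.43) and HOXA10 2.41-fold lower (2.09 to 2.79), whereas HOXB9 was at 24.1 against 70.3 CPM. The median stayed at percentile 0 among lists matched on expression, GC content and length in the same coarse bins. This argues against a bias of GC content or length, as far as those bins resolve it. The counting interval lay wholly below 1 for 16 members and wholly above 1 for 2. For the 7 called lower and the 1 called higher, the threshold and filter fix this in advance. For the members not called whose interval excluded 1, it argues against counting error alone. A difference between the cultures other than the drug stays open here too.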
